A study of Arabidopsis thaliana with 44 samples.

How the data were processed

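The deposited files, 1 per sample, list 34262 genes, and the 44 libraries were grouped by their labels alone. Per the file headers each file gives the TPM and the number of reads of each gene. The deposited read numbers are expected counts with fractions, and the deposited TPM values have the same sum in each library. Genome build TAIR10 is credited to the submitters' processing notes. The quantification program is not given in the sources used here. Gene symbols came from a table of assembly TAIR10.1 that matched 32548 of the identifiers and served for names only, so no coordinates are given. The labels' protocols name total RNA, the RNeasy kit, PSY5 at 1 uM and 2 library and instrument pairs (TruSeq v2 on a MiniSeq and NEBNext Ultra II on a NextSeq550), without saying which samples used which.

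Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (TMM factors, quasi-likelihood F tests, trended dispersion) in R 4.3.3. All groups of a tissue were in 1 fit, and shoot minus root differences came from a joint fit of roots and shoots. Genes needed a TPM of at least 1 in at least 3 libraries of roots or seedlings, or 4 of shoots. P-values were adjusted by the method of Benjamini and Hochberg within each comparison, and genes passed at an adjusted p below 0.05. The test planned before the values were seen was limma on log2(TPM + 1). It was replaced by edgeR because the read numbers are expected counts, and was kept as an alternative. Fold changes are log2 values ± SE, and levels are mean ± SD of TPM over libraries. The p-values measure spread between these libraries, which can be technical, since the labels do not say what separates replicates.

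For a gene without reads in 1 group, 3 reads over that group's libraries set a bound, given as at least so many fold. The bound covers counting error only. Genes with 1 to 3 reads in a group are given by level. Lists of genes were fixed before the data were examined, 25 lists over 556 loci: sulfated peptide pathway, salicylic acid response, jasmonate and wound response, stress transcription factors, pattern-triggered immunity, abscisic acid and dehydration response, oxidative stress and detoxification, indole and camalexin biosynthesis, heat shock and protein folding, hypoxia response, senescence and sugar starvation, cell expansion and cell wall loosening, cell division, photosynthesis (nuclear-encoded), root hair, endodermis (Casparian strip and suberin), root meristem, iron deficiency response, phosphate starvation response, circadian clock, auxin response, cytokinin response, anthocyanin and flavonoid biosynthesis, glucosinolate biosynthesis and reference genes. A list was tested with camera (limma 3.58.1) at a preset correlation of 0.01 if at least 5 members were tested, and again with an estimated correlation. Those p-values were adjusted over all lists and comparisons of a tissue. Photosynthesis genes in roots and root hair and endodermis genes in shoots were read as signs of carried-over tissue, and the clock list as a sign of harvest time. No root hair gene was tested in shoots. Median log2 fold changes cover the tested members.

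Genes were named by a rule made before the data were examined. TPST, PSYR1, PSYR2 and PSYR3 were named in each group. Each of 9 main comparisons gave the 10 called genes with the largest rise and the 10 with the largest fall, other comparisons 5 each way, where replicates did not overlap and 1 group had a mean of at least 5 TPM. Each list gave up to 4 called members with the smallest adjusted p. Of these, genes whose call held under every setting and with every library left out were preferred in the text. Near-identical gene copies can exchange reads, so values of single members of such families are uncertain.

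Alternatives chosen with the design were TPM without organelle genes, median-of-ratios factors, quantile normalization, the compared groups alone, a TPM filter of 5, no filter, no trend, the replicate number as a block, pseudocounts of 0.1 and 5, each library left out, an estimated correlation and the tpst-1 shoot libraries split 2 and 2. DESeq2 1.42.0 on the rounded counts and comparisons against 2 h were added after the data were seen. DESeq2 used a Wald test, and a likelihood-ratio test for any change over time. Simulated data for shared controls had no effect and the observed dispersion. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

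The edgeR test was tried on counts drawn from the fitted means, dispersions and library sizes, with 200 changed genes. It recovered 61.2%, 94% and 100% of genes changed by 1.5-, 2- and 4-fold in roots, 29.9%, 79.1% and 98.5% in shoots and 53.7%, 77.6% and 98.5% in seedlings. False calls were 6.08%, 3.5% and 4.38% of calls. The common biological coefficient of variation was 0.0588 in roots, 0.186 in shoots and 0.107 in seedlings. Loci with identifiers of the ENSRNA kind took up 0.08826 to 0.259% of reads in roots, 0.2615 to 1.643% in shoots and 0.4864 to 1.477% in seedlings. No 2 libraries of a group were identical.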

Results

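The 44 libraries came from plants labelled as 7 days old and formed 13 groups. Roots carried the labels tpst-1, tpst-1 with PSY5 and tpst/psyr1,2,3 (n = 3 each). Shoots carried the labels wild type, tpst-1, tpst-1 with PSY5, psyr1,2,3 and tpst/psyr1,2,3 (n = 4 each). Whole tpst-1 seedlings were sampled at 0 h, 2 h, 6 h, 24 h and 7 d of PSY5 (n = 3 each). TPST encodes the tyrosylprotein sulfotransferase that sulfates PSY and other small peptides, and PSYR1, PSYR2 and PSYR3 encode receptors of PSY peptides. After removal of weakly expressed genes, 19958 genes were tested in roots, 20723 in shoots and 21069 in seedlings.

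TPST transcript was not lost in libraries labelled tpst-1. Its level was 8.56 ± 0.605 TPM in wild-type shoots and 6.70 ± 1.59 TPM in shoots labelled tpst-1 (log2 fold change -0.20 ± 0.13, adjusted p = 0.395, n = 4 each). TPST was lower in shoots labelled tpst/psyr1,2,3 than in those labelled psyr1,2,3 (log2 fold change -0.78 ± 0.13, adjusted p = 0.00769, but 0.0531 by limma with a pseudocount of 0.1). It was also lower there than in wild type (-0.58 ± 0.14, adjusted p = 0.0107), which limma on log2(TPM + 1) did not call (adjusted p = 0.171). PSYR1 fell from 5.26 ± 0.560 TPM in wild type to 1.15 ± 0.461 TPM in psyr1,2,3 (-2.38 ± 0.21, adjusted p = 8.29e-07), and in tpst/psyr1,2,3 it reached 1.37 ± 0.151 TPM (-2.17 ± 0.21, adjusted p = 3e-07, against tpst-1). In roots, PSYR2 fell from 6.27 ± 0.562 TPM in tpst-1 to 2.37 ± 0.514 TPM in tpst/psyr1,2,3 (-1.44 ± 0.17, adjusted p = 1.14e-06, n = 3 each). In shoots PSYR2 was at 7.94 ± 0.884 TPM in wild type and 4.47 ± 0.973 TPM in psyr1,2,3 (adjusted p = 0.0185). That call was lost by limma on log2(TPM + 1) (adjusted p = 0.168) and without shoot wild type replicate 1 (0.0736), shoot psyr1,2,3 replicate 3 (0.0671) or replicate 4 (0.0794). Between tpst-1 and tpst/psyr1,2,3 shoots, at 5.99 ± 2.89 and 4.99 ± 0.366 TPM, PSYR2 did not pass (-0.52 ± 0.22, adjusted p = 0.107), but it passed without shoot tpst-1 replicate 1 (-0.77, adjusted p = 0.000295). PSYR3 moved the other way in the same roots, from 19.0 ± 0.906 to 60.5 ± 3.49 TPM (1.59 ± 0.08, adjusted p = 3.11e-12). The shoot level of PSYR3 was 8.69 ± 3.76 TPM in tpst/psyr1,2,3 and 2.93 ± 1.45 TPM in tpst-1. Replicate 1 of shoot tpst-1 stood apart from the other 3 in PSYR1 (2.33 TPM against 5.81 to 6.02) and PSYR2 (1.67 TPM against 7.24 to 7.55), and it is part of each tpst-1 shoot value. Gene totals do not show which part of a transcript was made, so the genotypes are given as labelled throughout.

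**Figure D1:**
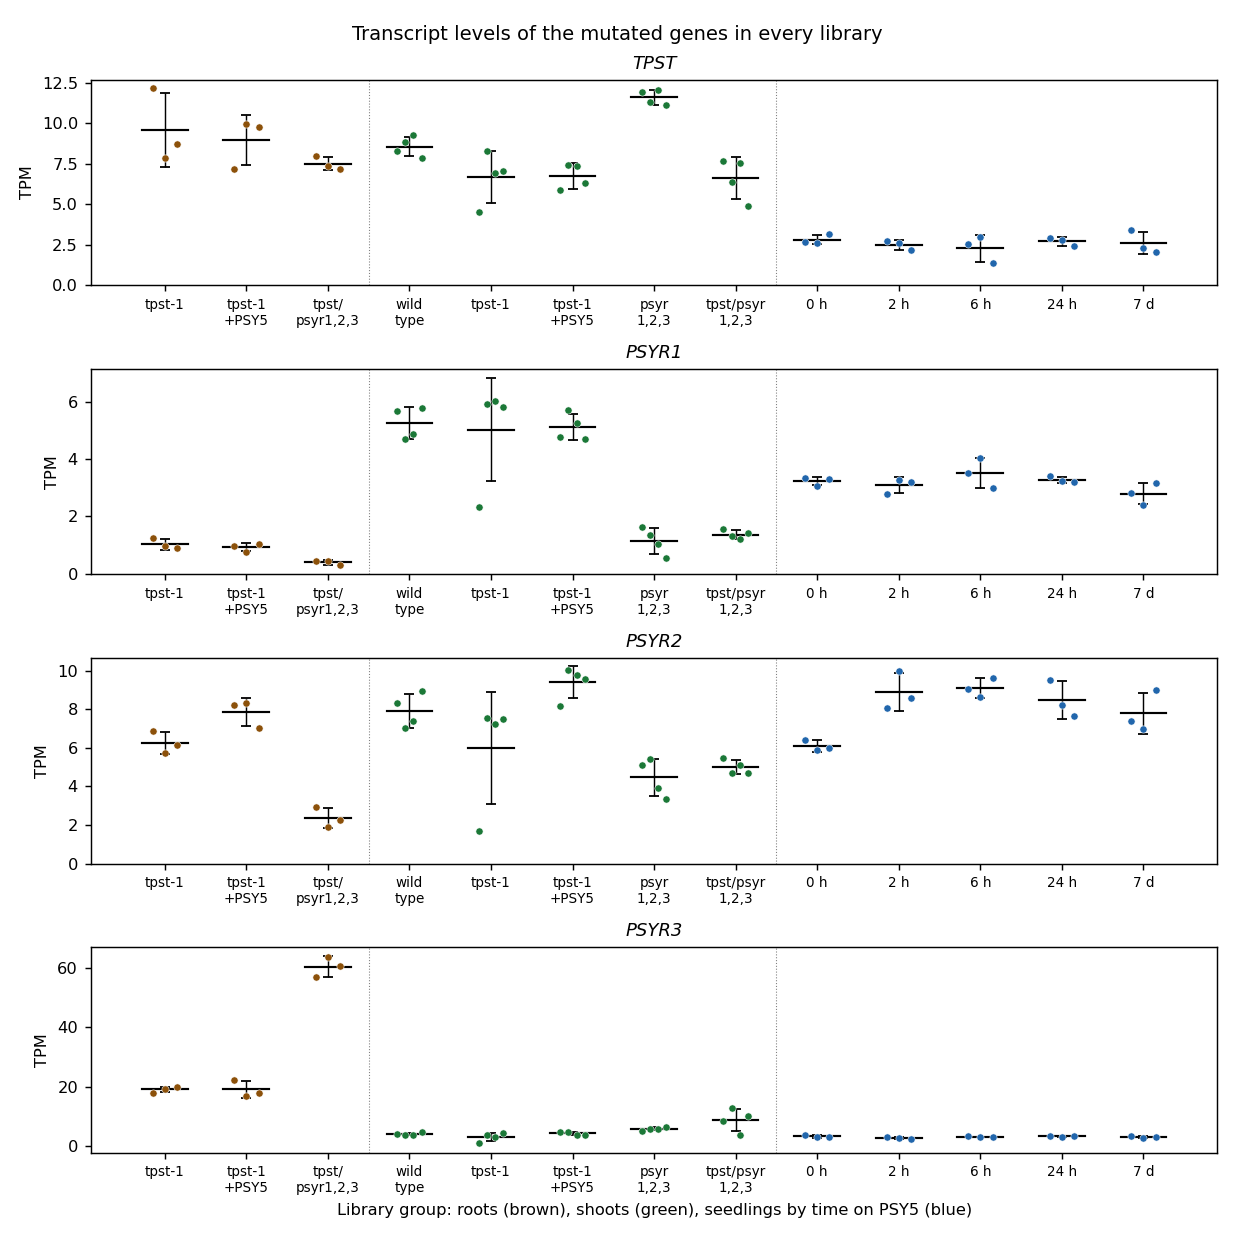
Abundance in TPM of TPST, PSYR1, PSYR2 and PSYR3 in the 13 groups of libraries. Points are libraries, and lines with bars are mean ± SD. PSYR3 in roots labelled tpst/psyr1,2,3 stood at 60.5 ± 3.49 TPM.

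How tpst-1 roots responded to PSY5 was asked first. Glucosinolate genes rose and iron-uptake genes fell. Many stress transcription factor genes fell as well, but as a list they did not pass with an estimated correlation (adjusted p = 0.215). UMAMIT17 rose from 2.92 ± 0.762 to 54.7 ± 3.12 TPM (log2 fold change 4.26 ± 0.15, adjusted p = 1.12e-14), a putative amino acid transporter, and MAM1 rose from 17.9 ± 2.73 to 98.5 ± 8.15 TPM (adjusted p = 3.82e-13), which acts in methionine chain elongation (n = 3 each). The trehalose-phosphate phosphatase gene TPPH rose from 0.224 ± 0.388 to 11.3 ± 1.85 TPM. The largest falls included the cell-wall invertase gene CWINV5 (log2 fold change -5.04 ± 0.34, adjusted p = 2.64e-10), and the transcription factor gene MYB2 fell from 5.84 ± 0.911 to 0.312 ± 0.541 TPM. AT3G46880 had no reads in the treated roots and was at least 16.3-fold lower. Of 19958 genes, 1500 rose and 1535 fell, 244 and 607 of them by more than 2-fold. Fewer genes passed with limma (2285, or 1942 without a mean-variance trend) and with DESeq2 (1871).

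Defence-related lists moved down in roots with PSY5. Of the stress transcription factors, 26 of 49 fell and 3 rose (median log2 fold change -0.98, 4 up and 28 down adjusted over the list alone, adjusted p = 0.215 with an estimated correlation). WRKY22 fell by 3.59 and ERF109 fell by 4.09 log2 units, and WRKY48 fell from 45.8 ± 12.3 to 8.10 ± 2.42 TPM (log2 fold change -2.45). Of the jasmonate and wound response genes, 13 of 23 fell and 2 rose (median log2 fold change -0.91, 2 up and 16 down adjusted over the list alone, adjusted p = 0.249 with an estimated correlation), with JAZ1 -1.70, MYC2 -1.32 and LOX4 -3.96. The pattern-triggered immunity list had the same direction, and 8 of 18 fell and 0 rose (median log2 fold change -0.71, 0 up and 10 down adjusted over the list alone, adjusted p = 0.156 with an estimated correlation), among them EXL7 -2.77, LYK5 -2.22 and MPK3 -1.19. Of the salicylic acid response genes, 8 of 19 fell and 2 rose (median log2 fold change -0.38, 3 up and 8 down adjusted over the list alone, adjusted p = 0.332 with an estimated correlation). For hypoxia response, 6 of 12 fell and 0 rose (median log2 fold change -0.64, 0 up and 7 down adjusted over the list alone, adjusted p = 0.101 with an estimated correlation), with HB1 -1.14 and ADH1 -1.34. For senescence and sugar starvation, 3 of 9 fell and 0 rose (median log2 fold change -0.40, 0 up and 3 down adjusted over the list alone, adjusted p = 0.0348 with an estimated correlation), led by ASN1 -3.94 and DIN10 -1.77. Under quantile normalization the last median was -0.18.

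Transcripts of iron-uptake genes fell in the same roots. The ferric-chelate reductase gene FRO2 fell from 26.9 ± 4.02 to 4.89 ± 1.60 TPM (log2 fold change -2.43 ± 0.17, adjusted p = 3.19e-10), and the iron transporter gene IRT1 fell from 73.9 ± 12.2 to 19.4 ± 3.1 TPM (log2 fold change -1.89 ± 0.13, adjusted p = 3.99e-10). Of the iron deficiency response genes, 15 of 21 fell and 0 rose (median log2 fold change -0.76, 0 up and 15 down adjusted over the list alone, adjusted p = 0.0065 with an estimated correlation). In the glucosinolate biosynthesis list, 12 of 16 rose and 0 fell (median log2 fold change 0.91, 13 up and 0 down adjusted over the list alone, adjusted p = 0.00875 with an estimated correlation), and BCAT4 and MAM3 rose by 1.62 and 1.41 log2 units. Endodermal barrier genes rose, SGN1 1.16, CASP1 0.92 and ESB1 0.90 among them, and of that list 12 of 21 rose and 2 fell (median log2 fold change 0.61, 14 up and 2 down adjusted over the list alone, adjusted p = 0.0258 with an estimated correlation). Of the cell division genes, 9 of 33 fell and 0 rose (median log2 fold change -0.22, 0 up and 14 down adjusted over the list alone, adjusted p = 0.0304 with an estimated correlation), with CYCD3;1 -1.08 and CYCA2;3 -0.66. In the cytokinin response list ARR4 -0.70, ARR5 -1.23 and ARR7 -1.39 fell, and in all 5 of 11 fell and 0 rose (median log2 fold change -0.41, 0 up and 6 down adjusted over the list alone, adjusted p = 0.0463 with an estimated correlation).

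In the cell expansion and cell wall loosening list the aquaporin genes PIP2;2 1.15, PIP2;1 0.94, TIP1;1 0.87 and PIP1;1 0.98 rose, but the list as a whole split. There, 12 of 37 fell and 10 rose (median log2 fold change 0.02, 10 up and 12 down adjusted over the list alone, adjusted p = 0.675 with an estimated correlation), its mean was -0.106, and its median turned negative under quantile normalization (-0.01). The root hair genes moved up, and 6 of 12 rose and 0 fell (median log2 fold change 0.43, 7 up and 0 down adjusted over the list alone, adjusted p = 0.249 with an estimated correlation), with ADF8 0.63 and EXPA18 0.49. Of the phosphate starvation response genes, 4 of 18 rose and 1 fell (median log2 fold change 0.25, 4 up and 1 down adjusted over the list alone, adjusted p = 0.249 with an estimated correlation), and of the circadian clock genes, which track harvest time as well as treatment, 7 of 19 rose and 0 fell (median log2 fold change 0.23, 7 up and 1 down adjusted over the list alone, adjusted p = 0.273 with an estimated correlation). By limma on log2(TPM + 1) the clock median was 0.15. In anthocyanin and flavonoid biosynthesis, 6 of 8 rose and 0 fell (median log2 fold change 0.33, 6 up and 0 down adjusted over the list alone, adjusted p = 0.362 with an estimated correlation). The other lists carried no call for the list as a whole. In the sulfated peptide pathway, 5 of 22 rose and 4 fell (7 up and 5 down adjusted over the list alone). Its median was -0.05 although the list test pointed up. In abscisic acid and dehydration response, 5 of 22 rose and 4 fell (6 up and 7 down adjusted over the list alone). Median and mean were 0.157 and -0.0332 in that list. In oxidative stress and detoxification, 8 of 28 rose and 4 fell (8 up and 4 down adjusted over the list alone). In indole and camalexin biosynthesis, 2 of 9 rose and 2 fell (3 up and 2 down adjusted over the list alone). Its median was 0.184 and its mean -0.0669, and the list test pointed down. In heat shock and protein folding, 1 of 17 fell and 0 rose (0 up and 4 down adjusted over the list alone). In auxin response, 2 of 11 rose and 2 fell (2 up and 5 down adjusted over the list alone). In root meristem, 1 of 7 rose and 0 fell (1 up and 0 down adjusted over the list alone). Among photosynthesis (nuclear-encoded) genes, counted in roots as a sign of shoot tissue, 4 of 37 rose and 2 fell (4 up and 3 down adjusted over the list alone). Among reference genes, which check the scaling, 2 of 7 rose and 0 fell (median log2 fold change 0.05, 3 up and 0 down adjusted over the list alone).

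Roots labelled tpst/psyr1,2,3 were compared with tpst-1 roots to ask what receptor loss changed where TPST was already mutant. Many of the genes that moved with PSY5 moved here too. UMAMIT17 rose from 2.92 ± 0.762 to 50.8 ± 0.0905 TPM (log2 fold change 4.08 ± 0.16, adjusted p = 2.18e-14), and MAM1 rose from 17.9 ± 2.73 to 118 ± 10.9 TPM (log2 fold change 2.69 ± 0.11, adjusted p = 6.02e-14) (n = 3 each). TPPH rose from 0.224 ± 0.388 to 18.6 ± 3.22 TPM and QQS from 0.790 ± 0.686 to 13.2 ± 5.17 TPM, with few reads at the lower level, and MRN1 rose too (log2 fold change 3.98 ± 0.17, adjusted p = 6.02e-14). ASN1, for asparagine synthetase (-5.98 ± 0.47, adjusted p = 2.74e-09), and CWINV5 (-5.23 ± 0.36, adjusted p = 2.99e-10) were among the largest falls. AT5G53486 had no reads in these roots and was at least 21.6-fold lower. In total 1576 genes rose and 1497 fell, 290 and 514 by more than 2-fold. With limma 2353 genes passed, or 1871 without a trend, and with DESeq2 1866.

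Stress transcription factors moved alike in these roots, where 27 of 49 fell and 2 rose (median log2 fold change -0.95, 3 up and 31 down adjusted over the list alone, adjusted p = 0.215 with an estimated correlation), with WRKY22 -3.21, ERF109 -3.72 and WRKY40 -3.12. Of the jasmonate and wound response genes, 12 of 23 fell and 3 rose (median log2 fold change -0.66, 4 up and 16 down adjusted over the list alone, adjusted p = 0.317 with an estimated correlation), and of the pattern-triggered immunity genes, 10 of 18 fell and 0 rose (median log2 fold change -0.60, 0 up and 11 down adjusted over the list alone, adjusted p = 0.215 with an estimated correlation). Of the iron deficiency response genes, 16 of 21 fell and 0 rose (median log2 fold change -0.88, 0 up and 16 down adjusted over the list alone, adjusted p = 0.0065 with an estimated correlation), with FRO2 -1.95, IRT1 -1.71 and NAS2 -1.15. In glucosinolate biosynthesis, 16 of 16 rose and 0 fell (median log2 fold change 1.12, 16 up and 0 down adjusted over the list alone, adjusted p = 0.0065 with an estimated correlation). Barrier genes rose (CASP1 1.15 and ESB1 1.13), and of the endodermis list 15 of 21 rose and 0 fell (median log2 fold change 0.70, 17 up and 1 down adjusted over the list alone, adjusted p = 0.00674 with an estimated correlation). Of senescence and sugar starvation, 4 of 9 fell and 0 rose (median log2 fold change -0.38, 1 up and 4 down adjusted over the list alone, adjusted p = 0.0258 with an estimated correlation). Of the hypoxia response genes, 6 of 12 fell and 0 rose (median log2 fold change -0.75, 0 up and 6 down adjusted over the list alone, adjusted p = 0.0811 with an estimated correlation), and of cytokinin response, 4 of 11 fell and 0 rose (median log2 fold change -0.42, 0 up and 5 down adjusted over the list alone, adjusted p = 0.0805 with an estimated correlation). In cell division, 4 of 33 fell and 0 rose (median log2 fold change -0.18, 0 up and 4 down adjusted over the list alone, adjusted p = 0.0764 with an estimated correlation), and CYCD3;1 fell by 0.88 log2 units. Among photosynthesis (nuclear-encoded) genes, 13 of 37 rose and 0 fell (median log2 fold change 0.63, 15 up and 0 down adjusted over the list alone, adjusted p = 0.362 with an estimated correlation). Root replicate 2 of tpst/psyr1,2,3 decided part of this, since without it 6 rose and the median was 0.37.

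The 2 root groups were then compared directly, to ask whether receptor loss and PSY5 left different transcriptomes. Few genes differed. AT1G78850 was at 16.3 ± 1.66 TPM in tpst/psyr1,2,3 roots and 202 ± 8.46 TPM in PSY5-treated tpst-1 roots (log2 fold change -3.71 ± 0.08, adjusted p = 1.32e-18, n = 3 each). PSYR3 was higher (1.56 ± 0.08, adjusted p = 4.48e-11) and PSYR2 lower (-1.79 ± 0.16, adjusted p = 8.58e-07) in tpst/psyr1,2,3. By edgeR 107 genes passed, 63 higher and 44 lower in tpst/psyr1,2,3, and 5 to 17 under 5 limma settings, or 253 without a filter on low values. The count fell past 1.5 times without root tpst-1 PSY5 replicate 2 (53), root tpst/psyr1,2,3 replicate 2 (47) and root tpst/psyr1,2,3 replicate 3 (63). Without root tpst-1 PSY5 replicate 1, 69 were higher and 72 lower. Of the photosynthesis (nuclear-encoded) genes, 3 of 37 were higher and 0 were lower (median log2 fold change 0.59, 22 up and 0 down adjusted over the list alone, adjusted p = 0.11 with an estimated correlation). Without root tpst/psyr1,2,3 replicate 2, 0 of these passed and the median was 0.35. Of the endodermis genes, 1 of 21 was higher and 0 lower (median log2 fold change 0.23, 3 up and 0 down adjusted over the list alone, adjusted p = 0.0357 with an estimated correlation).

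Across all tested root genes, the change with receptor loss and the change with PSY5 had a correlation of r = 0.746 (rank correlation 0.729). Both changes share the tpst-1 libraries, and simulated data without any effect gave a mean r of 0.506 from that sharing alone. In both, 1069 genes rose and 1044 fell, against 118 and 115 expected if calls were unrelated, and 2 genes passed in opposite directions.

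**Figure D2:**
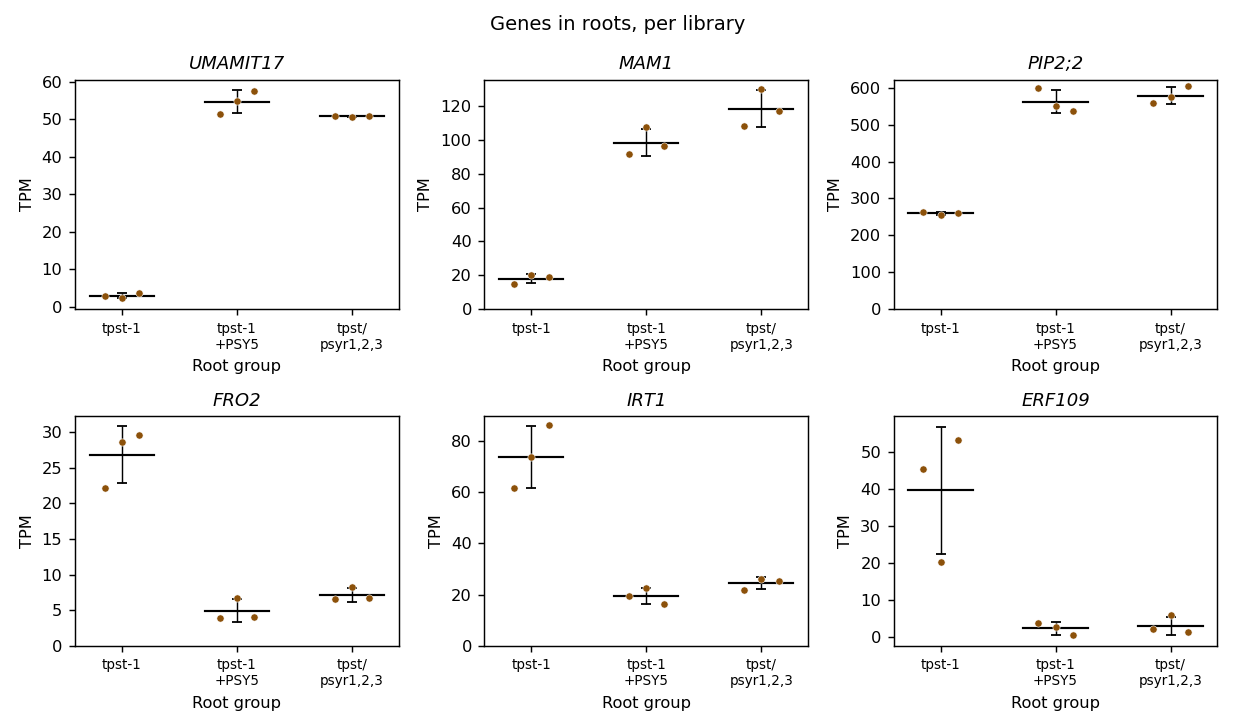
Abundance in TPM of UMAMIT17, MAM1, PIP2;2, FRO2, IRT1 and ERF109 in roots of the 3 labelled groups. Points are libraries and bars are mean ± SD. UMAMIT17 stood at 2.92 ± 0.762, 54.7 ± 3.12 and 50.8 ± 0.0905 TPM in tpst-1, PSY5-treated tpst-1 and tpst/psyr1,2,3.

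In shoots, tpst-1 was compared with wild type. Many stress, jasmonate and iron-deficiency genes rose, though the jasmonate list did not pass with an estimated correlation (adjusted p = 0.0892). ERF105 rose from 1.68 ± 0.455 to 44.4 ± 16.3 TPM (log2 fold change 4.85 ± 0.39, adjusted p = 2.47e-08) and WRKY18 rose from 9.85 ± 1.73 to 71.2 ± 40.5 TPM (log2 fold change 3.00 ± 0.26, adjusted p = 9.84e-08), both transcription factors of the stress list (n = 4 each). The iron-deficiency peptide gene IMA2 rose from 12 ± 7.57 to 66.5 ± 26.3 TPM (log2 fold change 2.72 ± 0.44, adjusted p = 0.000217). BHLH39 rose from 0.0515 ± 0.103 to 11.7 ± 6.99 TPM, and M17, a gene of late seed development, from 0.146 ± 0.291 to 31.2 ± 4.56 TPM. The oleosin gene OLEO1 rose from 0.321 ± 0.643 to 19.5 ± 3.86 TPM (log2 fold change 5.93 ± 0.64, adjusted p = 1.95e-06). M17 and OLEO1 were at only 0.0535 and 0 TPM in 0 h tpst-1 seedlings. Falls were fewer. MRD1 (log2 fold change -5.47 ± 0.59, adjusted p = 1.84e-06), the meiotic gene HEI10 (-2.55 ± 0.31, adjusted p = 6.91e-06) and the desaturase gene SAD6 (-2.20 ± 0.42, adjusted p = 0.00118) were among the largest. AT3G44070 had no reads in tpst-1 and was at least 655-fold lower. Of 20723 genes, 1465 rose and 443 fell, 835 and 56 by more than 2-fold. Between 1008 and 1053 genes passed under 4 limma settings, and 805 (741 up) with only these 2 groups in the fit. Under quantile normalization 1106 rose and 920 fell.

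Among stress transcription factors, 27 of 48 rose and 0 fell (median log2 fold change 1.49, 37 up and 0 down adjusted over the list alone, adjusted p = 0.0377 with an estimated correlation), with ERF104 3.09 and ZAT12 5.06. In jasmonate and wound response, 19 of 28 rose and 0 fell (median log2 fold change 1.99, 22 up and 0 down adjusted over the list alone, adjusted p = 0.0892 with an estimated correlation), including JAZ1 3.69, MYC2 2.53, VSP2 2.53 and AOC3 4.15. Of the iron deficiency response genes, 13 of 17 rose and 0 fell (median log2 fold change 1.57, 14 up and 0 down adjusted over the list alone, adjusted p = 0.0377 with an estimated correlation), including BHLH38 5.02 and ORG1 1.56. In abscisic acid and dehydration response, 12 of 26 rose and 0 fell (median log2 fold change 0.65, 14 up and 0 down adjusted over the list alone, adjusted p = 0.0973 with an estimated correlation), with RAB18 3.53 and LEA7 5.44. The seed storage genes CRA1, at 125 ± 31 TPM against 8.26 ± 16.5 TPM in wild type, and CRU3, at 36.1 ± 11.7 against 1.06 ± 2.13 TPM, were higher in the same shoots. Both were chosen after their values were seen, belong to no list and stood at 0.0906 and 0.0855 TPM in 0 h tpst-1 seedlings. In pattern-triggered immunity, 10 of 15 rose and 1 fell (median log2 fold change 1.23, 10 up and 1 down adjusted over the list alone, adjusted p = 0.0892 with an estimated correlation), with MPK3 1.23 and EXL7 2.35. In phosphate starvation response, 10 of 17 rose and 0 fell (median log2 fold change 1.15, 13 up and 0 down adjusted over the list alone, adjusted p = 0.0734 with an estimated correlation), led by AT4 2.51 and PS2 4.16. In anthocyanin and flavonoid biosynthesis, 10 of 14 rose and 0 fell (median log2 fold change 1.27, 11 up and 0 down adjusted over the list alone, adjusted p = 0.206 with an estimated correlation), with DFR 1.49 and 5MAT 1.97. In glucosinolate biosynthesis, 9 of 17 rose and 0 fell (median log2 fold change 0.65, 10 up and 1 down adjusted over the list alone, adjusted p = 0.198 with an estimated correlation), with SOT16 1.25. In salicylic acid response, 8 of 20 rose and 0 fell (median log2 fold change 0.55, 8 up and 0 down adjusted over the list alone, adjusted p = 0.219 with an estimated correlation), with WRKY70 2.58 and CBP60G 2.33. Its median was 0.52 with 3 genes that lacked reads in a group held at their bounds. Of the circadian clock genes, 5 of 19 fell and 1 rose (median log2 fold change -0.40, 1 up and 8 down adjusted over the list alone, adjusted p = 0.206 with an estimated correlation), with FKF1 -0.90. Several medians shrank by limma on log2(TPM + 1) and under quantile normalization. These were 0.91 and 0.96 for jasmonate (6 and 12 genes up), 0.86 and 0.92 for stress transcription factors, 0.76 and 0.87 for iron deficiency, 0.66 and 0.62 for phosphate starvation, 0.73 and 0.77 for anthocyanin and 0.28 and 0.31 for salicylic acid. The glucosinolate median was 0.42 by limma, and that of pattern-triggered immunity was 0.80 under quantile normalization. In hypoxia response, 2 of 11 fell and 1 rose (median log2 fold change -0.90, 1 up and 6 down adjusted over the list alone, adjusted p = 0.34 with an estimated correlation).

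Shoots labelled psyr1,2,3 were then compared with wild type. The glucosinolate gene CYP79F2 rose from 2.19 ± 0.742 to 7.47 ± 1.69 TPM (log2 fold change 1.61 ± 0.24, adjusted p = 0.000728), and the acid phosphatase gene PAP17 rose from 2.14 ± 0.815 to 7.29 ± 1.76 TPM (log2 fold change 1.63 ± 0.29, adjusted p = 0.00483) (n = 4 each). ASN1 fell from 49.8 ± 6.30 to 8.07 ± 1.87 TPM (log2 fold change -2.76 ± 0.36, adjusted p = 0.000218), and XTH15 fell from 8.48 ± 0.826 to 3.3 ± 0.429 TPM (log2 fold change -1.52 ± 0.20, adjusted p = 0.000164). CDT1 rose from 0.159 ± 0.318 to 18.0 ± 2.79 TPM, and MRD1 fell from 48.3 ± 1.06 to 0.284 ± 0.228 TPM. AT1G64795, absent from wild type, was at least 37.1-fold higher, and AT3G44070 and AT1G07887, absent from psyr1,2,3, at least 554-fold and 529-fold lower. CDT1, MRD1 and these 3 genes moved alike in tpst-1 shoots. In total 185 genes rose and 192 fell. The count was 1031 with only these groups in the fit, above the 805 of tpst-1 in such a fit, and 800 with DESeq2, and limma on TPM put 432 up and 71 down. It fell past 1.5 times without shoot wild type replicates 1 (113) and 2 (178). The same held for shoot psyr1,2,3 replicates 1 (249), 2 (234), 3 (185) and 4 (147). In glucosinolate biosynthesis, 7 of 17 rose and 0 fell (median log2 fold change 0.53, 9 up and 0 down adjusted over the list alone, adjusted p = 0.0709 with an estimated correlation), and in phosphate starvation response, 3 of 17 rose and 0 fell (median log2 fold change 0.85, 9 up and 0 down adjusted over the list alone, adjusted p = 0.0787 with an estimated correlation). For iron deficiency response, 2 of 17 rose and 0 fell (median log2 fold change 0.82, 7 up and 0 down adjusted over the list alone, adjusted p = 0.0892 with an estimated correlation), with PYE 1.12. In hypoxia response, 0 of 11 passed the test (median log2 fold change 0.70, 9 up and 0 down adjusted over the list alone, adjusted p = 0.122 with an estimated correlation), so all of those 9 depend on the smaller adjustment. Under quantile normalization the medians of phosphate starvation and iron deficiency genes were 0.46 and 0.50. The photosynthesis (nuclear-encoded) list had a median of -0.26, which became 0.03 under quantile normalization, and 0 of its genes passed.

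Receptor loss on the tpst-1 background in shoots was asked next, with tpst/psyr1,2,3 against tpst-1. Several stress genes that were higher in tpst-1 than in wild type fell here, in a comparison that shares the tpst-1 libraries. The stress list as a whole did not pass with an estimated correlation (adjusted p = 0.107). ERF105 fell from 44.4 ± 16.3 to 2.83 ± 1.22 TPM (log2 fold change -4.36 ± 0.37, adjusted p = 5.22e-08), and WRKY18 fell from 71.2 ± 40.5 to 10.6 ± 2.48 TPM (log2 fold change -3.12 ± 0.27, adjusted p = 5.75e-08) (n = 4 each). The anthocyanin gene DFR fell from 34.5 ± 8.91 to 5.25 ± 0.757 TPM (log2 fold change -3.13 ± 0.21, adjusted p = 3.93e-09), and the peptide gene IMA2 fell from 66.5 ± 26.3 to 15.2 ± 7.03 TPM (log2 fold change -2.62 ± 0.43, adjusted p = 0.000256). Rises included QQS 1.83 and IAA29 1.72, and falls ZAT12 -4.92 and BHLH38 -4.73, in log2 units. By edgeR 1073 genes rose and 2027 fell, 119 and 801 by more than 2-fold. This balance depended on the scale. Under 4 limma settings on TPM, 6531 to 7152 genes passed, and with a pseudocount of 1, 6000 rose and 820 fell. TPM scaling moved the median log2 fold change of all genes to 0.33 here, to 0.21 for PSY5 in shoots and to -0.14 for tpst-1 against wild type. Quantile normalization gave 1987 up and 1586 down. With only these groups in the fit 1065 passed, 911 of them down.

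Of the stress transcription factors, 25 of 48 fell and 3 rose (median log2 fold change -0.84, 4 up and 29 down adjusted over the list alone, adjusted p = 0.107 with an estimated correlation), including ERF104 -3.04 and WRKY22 -2.66. Of the jasmonate and wound response genes, 19 of 28 fell and 2 rose (median log2 fold change -1.34, 3 up and 19 down adjusted over the list alone, adjusted p = 0.235 with an estimated correlation), with JAZ1 -3.29, VSP2 -2.46 and AOS -1.17. Of the iron deficiency response genes, 11 of 17 fell and 0 rose (median log2 fold change -1.09, 0 up and 14 down adjusted over the list alone, adjusted p = 0.0877 with an estimated correlation), with IMA1 -2.93 and ORG1 -1.24. In anthocyanin and flavonoid biosynthesis, 11 of 14 fell and 0 rose (median log2 fold change -1.57, 0 up and 12 down adjusted over the list alone, adjusted p = 0.122 with an estimated correlation), with CHS -1.54, LDOX -2.60 and F3H -1.74. In pattern-triggered immunity, 9 of 15 fell and 0 rose (median log2 fold change -0.77, 1 up and 9 down adjusted over the list alone, adjusted p = 0.148 with an estimated correlation), with EXL7 -3.21 and CML38 -3.99. Among photosynthesis (nuclear-encoded) genes, 24 of 41 fell and 0 rose (median log2 fold change -0.45, 0 up and 34 down adjusted over the list alone, adjusted p = 0.293 with an estimated correlation), but under quantile normalization the median was 0.05 with 4 higher and 3 lower. In cell division, 7 of 33 rose and 3 fell (8 up and 3 down adjusted over the list alone, adjusted p = 0.547 with an estimated correlation), and in circadian clock, 7 of 19 fell and 4 rose (7 up and 7 down adjusted over the list alone, adjusted p = 0.71 with an estimated correlation). The clock balance turned with scaling, to 10 up and 0 down by limma on log2(TPM + 1) and 5 up and 4 down under quantile normalization, and in cell division limma put 16 up and 0 down. By limma the medians were -0.67 for jasmonate, -0.39 for stress transcription factors, -0.66 for iron deficiency, -0.28 for pattern-triggered immunity and -0.71 for anthocyanin genes (-0.99 under quantile normalization).

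PSY5 treatment of tpst-1 shoots was compared with untreated tpst-1 shoots. Iron-deficiency signalling genes were among the largest falls. IMA3 fell from 47.2 ± 19.2 to 0.618 ± 0.734 TPM (log2 fold change -6.33 ± 0.66, adjusted p = 2.15e-06) and IMA2 fell from 66.5 ± 26.3 to 2.28 ± 1.39 TPM (log2 fold change -5.10 ± 0.53, adjusted p = 2.07e-06) (n = 4 each). BHLH100, BHLH39, BHLH38 and BHLH101, for transcription factors of the iron-deficiency response, had no reads in treated shoots and were at least 202-, 193-, 175- and 96.5-fold lower. ERF105 fell from 44.4 ± 16.3 to 5.31 ± 1.5 TPM (log2 fold change -3.30). By edgeR 273 genes rose and 796 fell, 96 and 348 by more than 2-fold. The limma settings on TPM gave 431 to 656 (312 up and 265 down at a pseudocount of 1), and 377 passed with only these groups in the fit. The count moved past 1.5 times without shoot tpst-1 replicate 2 (1655), shoot tpst-1 PSY5 replicate 1 (661), shoot tpst-1 PSY5 replicate 2 (546) and shoot tpst-1 PSY5 replicate 3 (661).

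Of the iron deficiency response genes, 13 of 17 fell and 0 rose (median log2 fold change -1.70, 0 up and 13 down adjusted over the list alone, adjusted p = 0.00486 with an estimated correlation). Of the stress transcription factors, 20 of 48 fell and 3 rose (median log2 fold change -0.61, 7 up and 23 down adjusted over the list alone, adjusted p = 0.206 with an estimated correlation), with ERF104 -2.27 and ZAT10 -3.78. In jasmonate and wound response, 13 of 28 fell and 2 rose (median log2 fold change -1.31, 2 up and 21 down adjusted over the list alone, adjusted p = 0.184 with an estimated correlation), with AOS -1.22 and MYC2 -2.26. With 1 gene that lacked reads in a group held at its bound that median was -1.20. In pattern-triggered immunity, 6 of 15 fell and 1 rose (median log2 fold change -0.44, 1 up and 6 down adjusted over the list alone, adjusted p = 0.382 with an estimated correlation). The photosynthesis list moved down, and 15 of 41 fell and 0 rose (median log2 fold change -0.41, 0 up and 31 down adjusted over the list alone, adjusted p = 0.25 with an estimated correlation). Under quantile normalization the photosynthesis median was -0.02 with 1 gene lower, and by limma on log2(TPM + 1) it was -0.13 with 4 lower. By limma the medians were also -0.23 for stress transcription factors, -0.18 for pattern-triggered immunity and -0.59 for jasmonate genes, the last -0.78 under quantile normalization. In oxidative stress and detoxification, 7 of 26 rose and 1 fell (median log2 fold change 0.28, 7 up and 2 down adjusted over the list alone, adjusted p = 0.382 with an estimated correlation), with CSD2 0.82, and the median of the list was 0.47 by limma. In hypoxia response, 2 of 11 rose and 0 fell (median log2 fold change 0.66, 4 up and 1 down adjusted over the list alone, adjusted p = 0.228 with an estimated correlation), led by SAD6.

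**Figure D3:**
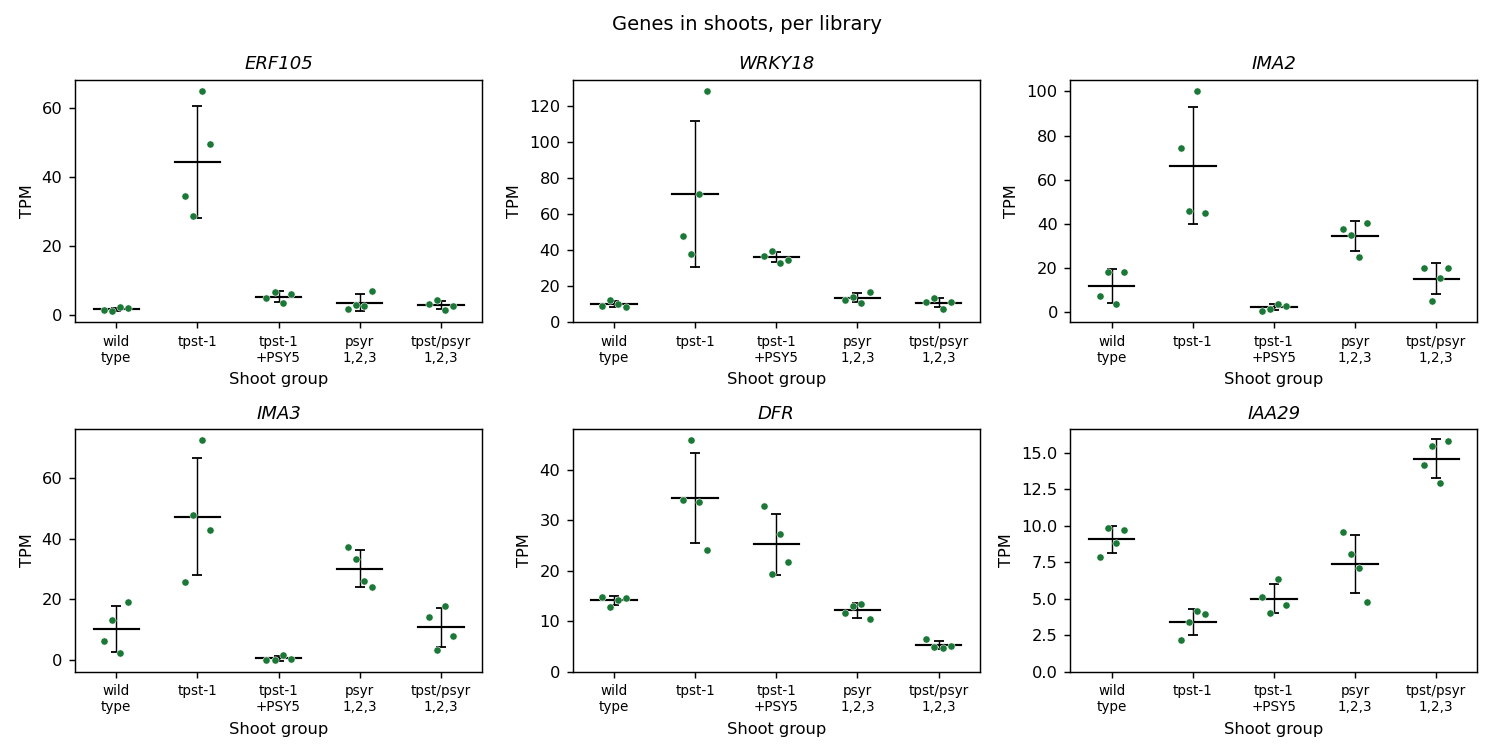
Abundance in TPM of ERF105, WRKY18, IMA2, IMA3, DFR and IAA29 in shoots of the 5 labelled groups. Points are libraries and bars are mean ± SD. ERF105 stood at 1.68 ± 0.455 TPM in wild type, 44.4 ± 16.3 in tpst-1 and 2.83 ± 1.22 in tpst/psyr1,2,3.

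Whether PSY5 and receptor loss moved the same shoot genes was asked as in roots. The correlation was r = 0.692 (rank correlation 0.738), and sharing the tpst-1 libraries alone gave a simulated mean of 0.496. The covariance was 0.326, against a simulated mean of 0.0833. With 2 of the 4 tpst-1 libraries as controls of each change the mean r was 0.287, from 0.245 to 0.339. In both comparisons 178 genes rose and 672 fell (14.1 and 77.9 expected if calls were unrelated), and 0 passed in opposite directions, counts that the shared libraries raise or lower. With those libraries split, 18 to 83 rose in both, 207 to 502 fell in both and 1 to 21 were opposite. Of the 1465 genes higher in tpst-1 than in wild type, 523 were lower with PSY5 and 895 were lower with receptor loss, 484 of them in both. Genes chosen as high in the shared tpst-1 libraries tend to fall against them. With those libraries split 2 and 2 the shares were 8.57 to 52.8% for PSY5 and 20.8 to 67.2% for receptor loss. Still above wild type were 410 of the genes with PSY5 and 249 with receptor loss.

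What tpst-1 added where the receptors were already mutant was asked with tpst/psyr1,2,3 against psyr1,2,3 shoots. Hypoxia genes fell. PCO1 fell from 14.3 ± 3.91 to 3.61 ± 0.619 TPM (log2 fold change -2.07 ± 0.29, adjusted p = 0.00146) and LBD41 fell from 31.5 ± 12.3 to 10.6 ± 2.92 TPM (log2 fold change -1.66 ± 0.28, adjusted p = 0.00769), which are an oxygen-sensing oxidase gene and a low-oxygen marker (n = 4 each). QQS rose from 6.03 ± 2.41 to 42.5 ± 5.30 TPM (log2 fold change 2.75). Of the hypoxia response genes, 5 of 11 fell and 0 rose (median log2 fold change -1.48, 0 up and 7 down adjusted over the list alone, adjusted p = 0.0273 with an estimated correlation). Their median was -0.89 by limma on log2(TPM + 1) and -0.95 under quantile normalization, each with 3 lower. In anthocyanin and flavonoid biosynthesis, 2 of 14 fell and 0 rose (median log2 fold change -0.61, 0 up and 5 down adjusted over the list alone, adjusted p = 0.1 with an estimated correlation). Of all genes, 35 rose and 60 fell. Under 4 limma settings 33 to 59 passed, with DESeq2 263 (124 up) and with only these groups in the fit 389 (198 up). It fell past 1.5 times without shoot psyr1,2,3 replicates 2 (36) and 4 (28) and shoot tpst/psyr1,2,3 replicates 1 (31), 2 (49) and 4 (54). Without shoot tpst/psyr1,2,3 replicate 3 the balance turned, with 67 up and 41 down.

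Distance from wild type was asked for shoots labelled tpst/psyr1,2,3. SAG13, a senescence marker, rose from 0.285 ± 0.328 to 8.60 ± 6.2 TPM (log2 fold change 4.66 ± 0.67, adjusted p = 0.000239, n = 4 each), and LHY, a clock gene, changed by -1.21 ± 0.12, adjusted p = 3.18e-06. In glucosinolate biosynthesis, 9 of 17 rose and 0 fell (median log2 fold change 0.82, 10 up and 0 down adjusted over the list alone, adjusted p = 0.0704 with an estimated correlation), in phosphate starvation response, 9 of 17 rose and 0 fell (median log2 fold change 0.94, 11 up and 0 down adjusted over the list alone, adjusted p = 0.0734 with an estimated correlation), and in abscisic acid and dehydration response, 10 of 26 rose and 0 fell (median log2 fold change 0.69, 14 up and 0 down adjusted over the list alone, adjusted p = 0.0892 with an estimated correlation). In photosynthesis (nuclear-encoded), 17 of 41 fell and 0 rose (median log2 fold change -0.42, 0 up and 32 down adjusted over the list alone, adjusted p = 0.206 with an estimated correlation). That fall depended on the scale, since the median was -0.02 with 1 gene lower under quantile normalization and -0.20 with 7 lower by limma on log2(TPM + 1). The phosphate starvation median was 0.47 under quantile normalization. Of the seed genes, OLEO1 was higher too (2.80 ± 0.73, adjusted p = 0.0207), while CRA1, CRU3, OLEO2, M17 and PER1 did not pass. Counts were 745 up and 714 down by edgeR, but 1549 up and 197 down by limma on TPM, and 2673 genes passed with only these groups in the fit. The edgeR count fell past 1.5 times without shoot wild type replicate 1 (845) and shoot tpst/psyr1,2,3 replicates 1 (909) and 2 (924).

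The same distance from wild type was asked for PSY5-treated tpst-1 shoots. WRKY18 remained above wild type, at 35.9 ± 2.87 against 9.85 ± 1.73 TPM (log2 fold change 1.80 ± 0.26, adjusted p = 0.00025, n = 4 each), and IMA3 was below it, at 0.618 ± 0.734 against 10.3 ± 7.52 TPM (-4.00 ± 0.68, adjusted p = 0.00113). Among stress transcription factors, 16 of 48 rose and 1 fell (median log2 fold change 0.93, 32 up and 2 down adjusted over the list alone, adjusted p = 0.0892 with an estimated correlation). In glucosinolate biosynthesis, 11 of 17 rose and 0 fell (median log2 fold change 0.76, 13 up and 0 down adjusted over the list alone, adjusted p = 0.0643 with an estimated correlation). In oxidative stress and detoxification, 12 of 26 rose and 0 fell (median log2 fold change 0.60, 14 up and 0 down adjusted over the list alone, adjusted p = 0.0643 with an estimated correlation). In salicylic acid response, 7 of 20 rose and 0 fell (median log2 fold change 1.14, 14 up and 0 down adjusted over the list alone, adjusted p = 0.0892 with an estimated correlation). Of the iron deficiency response genes, 3 of 17 fell and 0 rose (median log2 fold change -0.57, 0 up and 5 down adjusted over the list alone, adjusted p = 0.171 with an estimated correlation), a median of -0.35 with 4 genes that lacked reads in a group held at their bounds. By limma on log2(TPM + 1) and under quantile normalization the medians were 0.70 and 0.54 for salicylic acid and -0.21 and -0.35 for iron deficiency. Of all genes, 734 rose and 323 fell. With only these groups in the fit 2388 passed, and quantile normalization gave 593 up and 412 down. The count fell past 1.5 times without shoot wild type replicate 1 (587) and shoot tpst-1 PSY5 replicates 2 (634) and 3 (655).

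Whether the effect of tpst-1 differed between receptor-mutant and receptor-intact shoots was tested as an interaction. Negative values mean a smaller rise, or a fall, where the receptors were mutant. ERF105 had an interaction of -5.30 ± 0.56, adjusted p = 6.26e-06 (n = 4 in each of 4 groups). WRKY18 (-3.44 ± 0.37, adjusted p = 8.47e-06), IMA1 (-4.47 ± 0.66, adjusted p = 0.000289) and DFR (-2.74 ± 0.29, adjusted p = 6.01e-06) were negative too, and IAA29 (2.17 ± 0.27, adjusted p = 3.93e-05) was positive. Of the stress transcription factors, 20 of 48 were negative and 0 were positive (median log2 fold change -1.14, 0 up and 27 down adjusted over the list alone, adjusted p = 0.0485 with an estimated correlation). Of iron deficiency response genes, 12 of 17 were negative and 0 positive (median log2 fold change -1.58, 0 up and 12 down adjusted over the list alone, adjusted p = 0.00845 with an estimated correlation). In anthocyanin and flavonoid biosynthesis, 8 of 14 were negative and 0 positive (median log2 fold change -2.05, 0 up and 13 down adjusted over the list alone, adjusted p = 0.0704 with an estimated correlation). In pattern-triggered immunity, 5 of 15 were negative and 0 positive (median log2 fold change -1.16, 0 up and 10 down adjusted over the list alone, adjusted p = 0.0892 with an estimated correlation), and in jasmonate and wound response, 4 of 28 were negative and 0 positive (median log2 fold change -1.56, 0 up and 15 down adjusted over the list alone, adjusted p = 0.206 with an estimated correlation). Medians were smaller by limma on log2(TPM + 1) and under quantile normalization, at -0.63 and -0.68 for stress transcription factors, -1.27 and -1.36 for anthocyanin, -0.51 and -0.61 for pattern-triggered immunity and -0.82 and -0.94 for jasmonate genes. The interaction passed for 575 genes, 74 positive and 501 negative. With limma 230 to 307 passed under 4 settings, and under quantile normalization 132 were positive and 400 negative.

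Whole tpst-1 seedlings were followed from 0 h through 2 h, 6 h, 24 h and 7 d of PSY5, to ask which genes moved with time on the peptide. No untreated library stood beside the later times, so time and handling run together with PSY5. Low-oxygen genes fell at once and stayed down. LBD41 stood at 367 ± 9.43, 4.44 ± 1.29, 4.53 ± 0.315, 18 ± 7.87 and 62.0 ± 25.8 TPM in turn (n = 3 each). At 2 h its log2 fold change was -6.41 ± 0.29, adjusted p = 7.32e-13. PCO1 fell from 64.9 ± 5 to 3.84 ± 1.38 TPM by 2 h, and ERF105 fell from 60.0 ± 8.14 to 2.69 ± 0.727 TPM. The glucosinolate regulator gene MYB28 rose from 16.4 ± 1.43 to 44.6 ± 2.61 TPM by 2 h (adjusted p = 1.6e-10). Against 0 h, 954 genes rose and 1687 fell at 2 h, 1242 and 1804 at 6 h, 1145 and 1819 at 24 h, and 1798 and 2284 at 7 d. Any change over time passed for 5087 genes, and with limma for 3497, or 3341 without a trend. Under quantile normalization 1552 rose and 1411 fell at 6 h, and 1922 rose and 1777 fell at 7 d. Against 2 h in place of 0 h, a comparison chosen after the values were seen, 4 genes passed at 6 h, 646 at 24 h and 2108 at 7 d.

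Counts for the lists are given in the order 2 h, 6 h, 24 h and 7 d. Of the hypoxia response genes, 11, 12, 12 and 12 of 12 fell and 0, 0, 0 and 0 rose (12, 12, 12 and 12 and 0, 0, 0 and 0 adjusted over the list alone, medians -3.11, -3.57, -3.53 and -2.67, adjusted p = 0.00242, 0.00218, 0.00218 and 0.00339 with an estimated correlation). Of the stress transcription factors, 32, 34, 33 and 36 of 50 fell and 0, 0, 0 and 2 rose (36, 37, 36 and 38 and 1, 0, 1 and 2 adjusted over the list alone, medians -1.37, -1.50, -1.53 and -1.22, adjusted p = 1.03e-05, 1.03e-05, 2.19e-05 and 4.94e-05 with an estimated correlation), WRKY33 among them (-2.44, -2.68, -2.45, -1.71). In pattern-triggered immunity, 13, 11, 14 and 14 of 21 fell and 0, 0, 0 and 0 rose (14, 13, 17 and 16 and 1, 0, 0 and 0 adjusted over the list alone, adjusted p = 0.00218, 0.00218, 0.00175 and 0.00242 with an estimated correlation). In heat shock and protein folding, 9, 11, 10 and 11 of 16 fell and 0, 0, 1 and 0 rose (11, 12, 12 and 13 and 1, 0, 1 and 0 adjusted over the list alone, adjusted p = 0.00491, 0.00244, 0.0104 and 0.00228 with an estimated correlation), with HSP101 at -1.40 and -1.33 at 2 h and 7 d.

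In salicylic acid response, 10, 12, 19 and 21 of 25 fell and 0, 0, 0 and 0 rose (12, 16, 21 and 23 and 0, 0, 0 and 1 adjusted over the list alone, adjusted p = 0.141, 0.0796, 0.0222 and 0.0141 with an estimated correlation), and WRKY70 fell at each time (-2.14, -2.38, -2.31, -2.23). In glucosinolate biosynthesis the direction was up, and 2, 2, 0 and 1 of 17 fell and 8, 10, 14 and 15 rose (2, 2, 1 and 1 and 9, 14, 14 and 15 adjusted over the list alone, adjusted p = 0.147, 0.0658, 0.0141 and 0.00857 with an estimated correlation). For senescence and sugar starvation, 4, 5, 5 and 4 of 10 fell and 0, 1, 1 and 2 rose (6, 5, 5 and 4 and 0, 1, 1 and 2 adjusted over the list alone, adjusted p = 0.0104, 0.0141, 0.0106 and 0.147 with an estimated correlation). Of the photosynthesis genes, 0, 0, 0 and 0 of 41 fell and 1, 15, 6 and 39 rose (0, 0, 1 and 0 and 0, 23, 13 and 39 adjusted over the list alone, adjusted p = 0.645, 0.485, 0.645 and 0.112 with an estimated correlation). For jasmonate and wound response, 14 of 29 fell and 5 rose (median log2 fold change -0.55, 5 up and 17 down adjusted over the list alone, adjusted p = 0.489 with an estimated correlation) at 7 d, when CYP94C1 was at -3.30 and the defensin genes PDF1.2A, PDF1.2B and PDF1.3 at 3.00, 3.62 and 3.14, near-identical copies whose single values are uncertain. The dehydration gene RAB18 rose by 5.93 log2 units at 6 h, when in abscisic acid and dehydration response 10 of 21 rose and 1 fell (median log2 fold change 0.32, 10 up and 1 down adjusted over the list alone, adjusted p = 0.0827 with an estimated correlation).

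**Figure D4:**
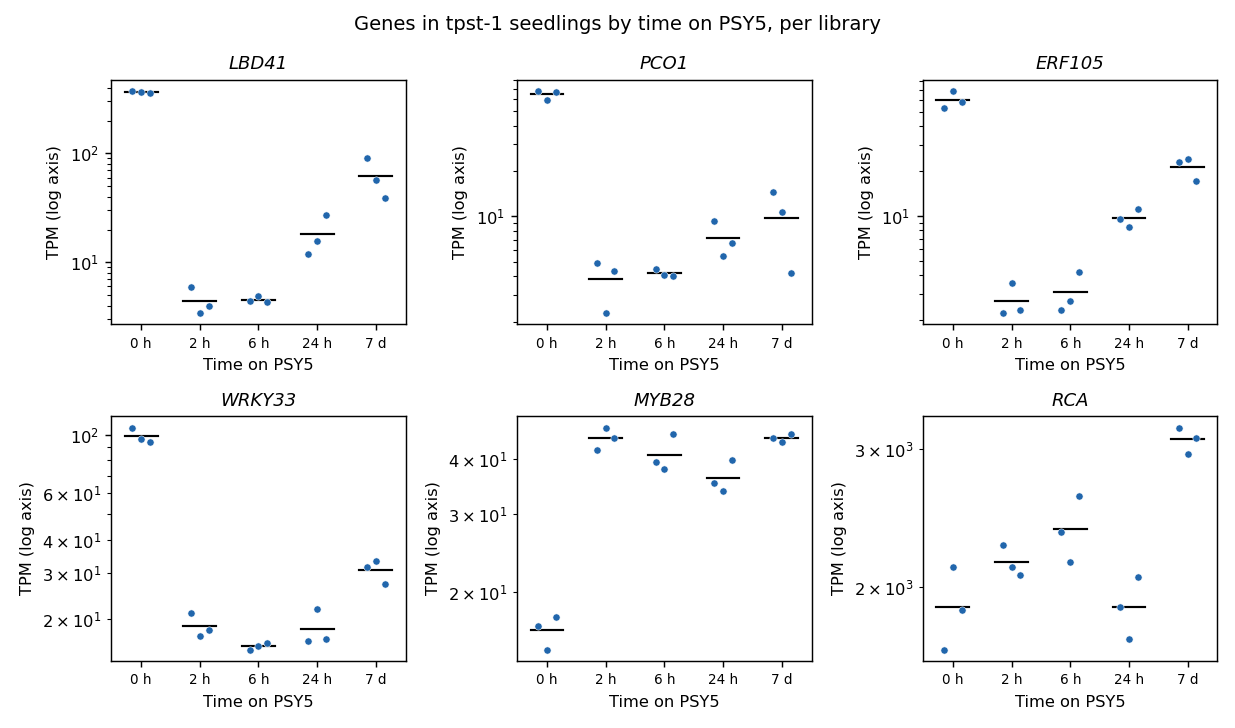
Abundance in TPM, on a log scale, of LBD41, PCO1, ERF105, WRKY33, MYB28 and RCA in tpst-1 seedlings at 0 h, 2 h, 6 h, 24 h and 7 d of PSY5. Points are libraries and short horizontal lines are the means. LBD41 went from 367 ± 9.43 TPM at 0 h to 4.44 ± 1.29 TPM at 2 h.

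Whether PSY5 acted differently in shoots and roots of tpst-1 was tested in a joint fit of both tissues. Root libraries held at most 4.13 M reads and shoot libraries at least 8.61 M, with common biological coefficients of variation of 0.0588 and 0.186. Which kit served which tissue is not given in the sources used here, so tissue cannot be parted from depth or kit. Positive differences mean a higher value in shoots. IMA2 fell with PSY5 in shoots, and its difference was -4.81 ± 0.87, adjusted p = 0.000996 (n = 4 in shoots and 3 in roots per group). The aquaporin genes PIP1;1 (-1.37 ± 0.14, adjusted p = 5.03e-07) and PIP2;2 (-1.58 ± 0.17, adjusted p = 5.81e-07) and the glucosinolate gene MAM1 (-1.96 ± 0.27, adjusted p = 3.64e-05) had lower effects in shoots, and ASN1 (3.60 ± 0.75, adjusted p = 0.0041) and SAD6 (2.97 ± 0.68, adjusted p = 0.00835) higher ones. In iron deficiency response, 5 of 16 were lower and 0 higher (median log2 fold change -1.26, 0 up and 10 down adjusted over the list alone, adjusted p = 0.0568 with an estimated correlation). In glucosinolate biosynthesis, 7 of 16 were lower and 0 higher (median log2 fold change -0.82, 0 up and 10 down adjusted over the list alone, adjusted p = 0.0844 with an estimated correlation). In hypoxia response, 5 of 11 were higher and 0 lower (median log2 fold change 1.44, 8 up and 0 down adjusted over the list alone, adjusted p = 0.0568 with an estimated correlation). By limma on log2(TPM + 1) and under quantile normalization the medians were -0.58 and -0.81 for iron deficiency and -0.42 and -0.54 for glucosinolate genes. The difference passed for 286 genes upward and 569 downward. By limma on TPM 541 passed upward and 195 downward, and 458 passed with only these groups in the fit. The count fell past 1.5 times without root tpst-1 replicates 1 (561), 2 (520) and 3 (542). The same held for root tpst-1 PSY5 replicates 1 (568) and 2 (531).

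Receptor loss in tpst-1 was put to the same question. IAA29 (3.42 ± 0.64, adjusted p = 0.000859) and ASN1 (4.92 ± 1.05, adjusted p = 0.00335) had higher effects in shoots, and MAM1 (-2.60 ± 0.27, adjusted p = 2.82e-07), PIP2;1 (-1.80 ± 0.18, adjusted p = 1.15e-07), CHS (-1.61 ± 0.26, adjusted p = 0.000178) and LHY (-1.36 ± 0.19, adjusted p = 2.65e-05) lower ones. Among photosynthesis (nuclear-encoded) genes, 20 of 37 were lower and 0 higher (median log2 fold change -1.04, 0 up and 28 down adjusted over the list alone, adjusted p = 0.143 with an estimated correlation). In glucosinolate biosynthesis, 8 of 16 were lower and 0 higher (median log2 fold change -0.85, 0 up and 13 down adjusted over the list alone, adjusted p = 0.0568 with an estimated correlation). By limma on log2(TPM + 1) the medians were -0.61 for photosynthesis (-0.50 under quantile normalization), and -0.38 for glucosinolate genes. Upward differences passed for 419 genes and downward ones for 902. By limma on TPM 1940 were upward and 387 downward, 2070 to 2903 genes passed under 4 limma settings, and 619 with only these groups in the fit. By edgeR the count fell past 1.5 times without root tpst-1 replicate 1 (865), root tpst-1 replicate 2 (822) and root tpst/psyr1,2,3 replicate 2 (854).

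Changes with PSY5 were last compared between libraries that share none. How long the treated roots and shoots were exposed is not given in the sources used here. Root and shoot changes had r = 0.155 (rank correlation 0.011), root and 7 d seedling changes r = 0.275 (0.22), and shoot and 7 d seedling changes r = 0.0761 (0.047). In root and shoot, 51 genes rose in both and 265 fell in both (16.7 and 51.1 expected if calls were unrelated), and 77 passed in opposite directions, 53 of them up in roots (47.1 expected) and 24 down (18.1 expected). In root and 7 d seedling, 320 rose in both and 595 fell in both (117 and 161 expected), and 200 were opposite, 136 up in roots (156 expected) and 64 down (121 expected). In shoot and 7 d seedling, 45 rose in both and 300 fell in both (23.2 and 81.9 expected), and 165 were opposite, 64 up in shoots (29.3 expected) and 101 down (64.8 expected).

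**Figure D5:**
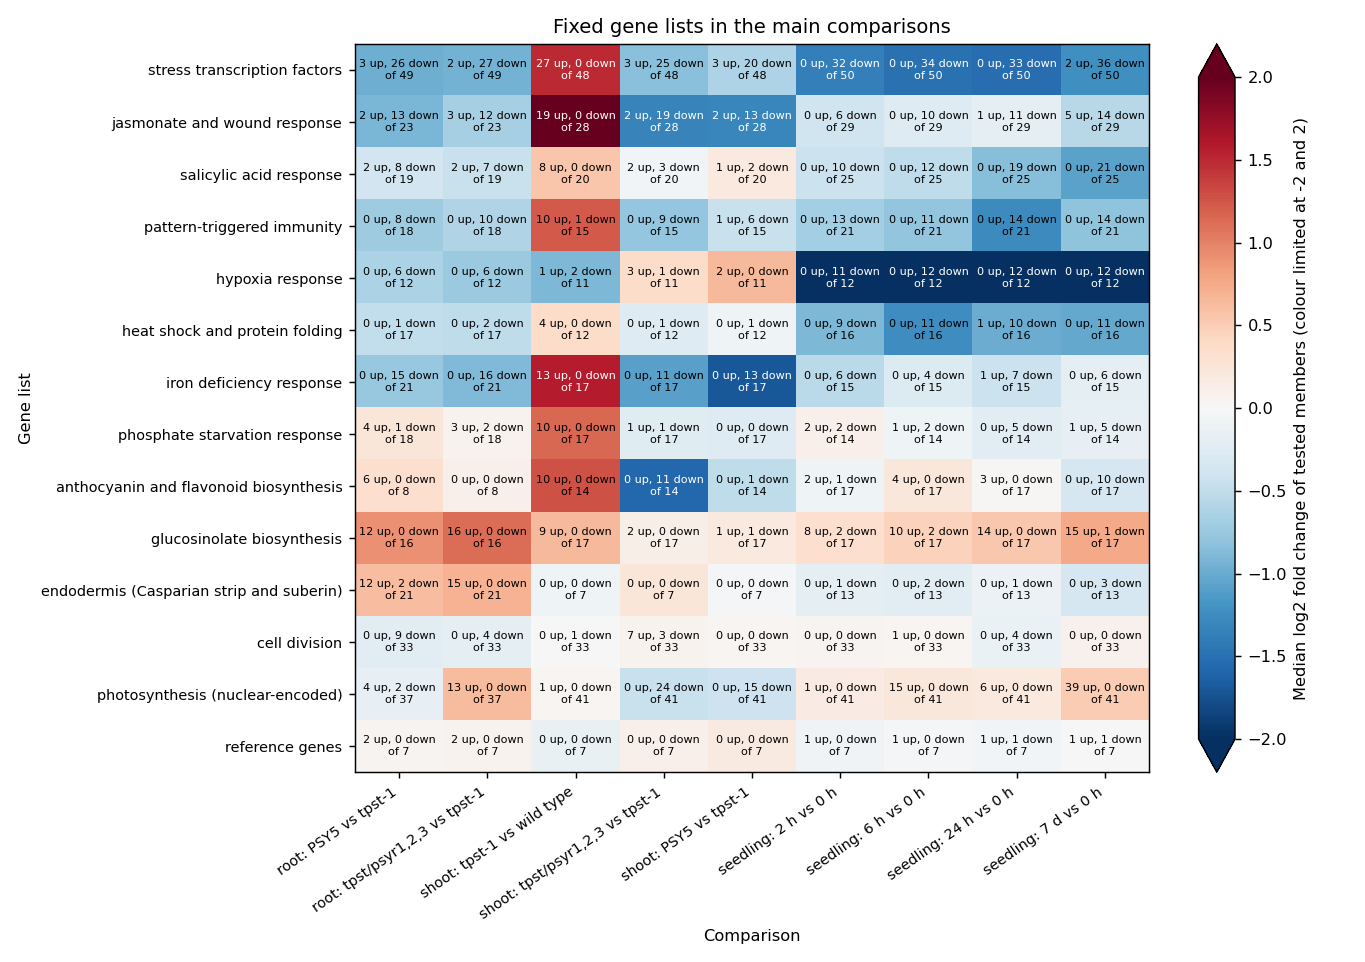
Median log2 fold change of 14 gene lists in the 9 main comparisons, as colour limited at -2 and 2, with the numbers of genes that rose and fell in each cell. Hypoxia genes in seedlings had medians of -3.11 at 2 h and -2.67 at 7 d.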

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

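All tests of explanations here were chosen after the result was seen, except the count of shared 31-mers. Dixon's test marks about 1 group in 20 by chance.

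Hypoxia genes were high in the 0 h seedlings, and the state of the 0 h seedlings at harvest is a candidate explanation. Of 12 such genes, 11 had a 0 h level above both untreated tpst-1 groups, LBD41 with 367 TPM against 10.8 in roots and 10 in shoots. Time of day stays open, since the 24 h seedlings (median log2 fold change -3.53) also had PSY5. A PSY5 effect stays open, since the median was 0.655 with PSY5 in tpst-1 shoots and -0.64 in roots. Untreated seedlings at the later times could separate these.

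In all, 9 genes parted wild-type shoots from every other shoot group, among them AT3G06715, AT3G44070, AT1G64795 and MRD1. A variant between the seed stocks of the wild type and the mutant lines could account for 6 of them, in which all 24 root and seedling libraries stood on the mutant side. Loss of sulfated peptide signalling stays open, since those libraries carry mutant labels too. With the genes chosen again without the PSY5-treated shoots, PSY5 moved 1 of 11 back toward wild type, ATSDI1 (log2 fold change -2.30, adjusted p = 7.31e-05), and 0 further away, but it replaces 1 of the peptides that TPST sulfates. Reads shared with near-identical copies are argued against by a median of 0% of 31-mers found elsewhere. Apart from the rest in the same way were 39 genes for tpst-1, 0 for PSY5-treated tpst-1, 0 for psyr1,2,3 and 1 for tpst/psyr1,2,3.

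Photosynthesis genes were higher in tpst/psyr1,2,3 roots than in PSY5-treated roots. Shoot tissue carried into the root libraries is a candidate explanation, but the median share was 0.0458% of the shoot level, and 40.2% of 82 abundant shoot transcripts rose by under 0.1 of it. By library that share was 0.0505, 0.228 and 0.0505% in tpst/psyr1,2,3, 0.047, 0 and 0.0255% in PSY5-treated tpst-1 and 0.0386, 0.0582 and 0.117% in tpst-1. Without root replicate 2 of tpst/psyr1,2,3, 0 genes of the list passed in place of 3. Receptor loss stays open, since the list median in tpst/psyr1,2,3 shoots against tpst-1 depended on the scale, with -0.453 by edgeR and 0.0512 under quantile normalization.

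In shoot tpst-1 replicate 1 the mitochondrial share of reads was 0.0224%, against 0.00264 to 0.00452% in the other 3 libraries. The same library had 2.33 TPM of PSYR1 (5.81 to 6.02 in the others) and 1.67 TPM of PSYR2 (7.24 to 7.55). Its TMM factor was 0.777 (0.961 to 1.03), and its 10 most abundant genes held 16.3% of reads (8.33 to 10.3%). Without it 2051 genes passed in tpst-1 against wild type, and 3151 in tpst/psyr1,2,3 against tpst-1. In shoot tpst-1 PSY5 replicate 1 the 10 most abundant genes held 7.66% of reads, against 9.23 to 9.48% in the others. Of 45 groups of values tested, 4 had a library apart. The PSY5 effect differed between shoots and roots for 855 genes and the receptor-loss effect for 1321, and the interaction passed for 575.

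Libraries of each comparison were also split in other ways and tested with limma. The labelled split gave the most genes each time, and counts are given with the highest other split in brackets. With 10 splits, too few for a share under 0.05, they were 2285 (5) for PSY5 in roots, 2353 (5) for receptor loss in roots, 17 (6) for receptor loss against PSY5 in roots, 2106 (3) for 2 h, 2427 (3) for 6 h, 2431 (3) for 24 h and 3044 (2) for 7 d. With 35 splits they were 6820 (61) for tpst/psyr1,2,3 against tpst-1, 577 (3) for PSY5 in shoots and 59 (1) for tpst/psyr1,2,3 against psyr1,2,3. Against wild type they were 1052 (9) for tpst-1, 503 (3) for psyr1,2,3, 1746 (2) for tpst/psyr1,2,3 and 776 (13) for PSY5-treated tpst-1. With 100 drawn splits they were 274 (29) for the interaction and 3497 (1317) for any change over time. For shoot minus root effects they were 736 (687) for PSY5 and 2327 (1709) for receptor loss. Those other splits moved 6 and 4 libraries and can keep treatment effects, so they set no chance level.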

How the results depend on the processing

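Counts that moved past 1.5 times are given with the edgeR count in brackets. Under limma with pseudocounts of 1, 0.1 and 5, with quantile normalization and without a trend, they were 17, 16, 13, 16 and 5 for receptor loss against PSY5 in roots (107). With these settings apart from quantile normalization, they were 1052, 1040, 1053 and 1008 for tpst-1 against wild type (1908), 6820, 6531, 7152 and 6717 for tpst/psyr1,2,3 against tpst-1 (3100), 577, 431, 656 and 552 for PSY5 in shoots (1069), 59, 33, 56 and 42 for tpst/psyr1,2,3 against psyr1,2,3 (95), 274, 230, 307 and 258 for the interaction (575) and 2327, 2070, 2903 and 2234 for the shoot minus root receptor-loss effect (1321). Past 1.5 times by limma without a trend, but not with it, were 1942 for PSY5 in roots (3035), 1871 for receptor loss in roots (3073) and 3341 for any change over time (5087).

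With the compared groups alone there were 805 for tpst-1 against wild type (1908), 1031 for psyr1,2,3 against wild type (377), 1065 for tpst/psyr1,2,3 against tpst-1 (3100), 377 for PSY5 in shoots (1069), 389 for tpst/psyr1,2,3 against psyr1,2,3 (95), 2673 for tpst/psyr1,2,3 against wild type (1459), 2388 for PSY5-treated tpst-1 against wild type (1057), 458 for the shoot minus root PSY5 effect (855) and 619 for the shoot minus root receptor-loss effect (1321). DESeq2 gave 1871 for PSY5 in roots (3035), 1866 for receptor loss in roots (3073), 800 for psyr1,2,3 against wild type (377) and 263 for tpst/psyr1,2,3 against psyr1,2,3 (95). Without a filter the count was 253 for receptor loss against PSY5 in roots (107). Against 2 h the counts were 4 for 6 h (3046), 646 for 24 h (2964) and 2108 for 7 d (4082).

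Scaling moved the balance of genes up and down by more than 10 percentage points in these cases. Quantile normalization gave 1106 and 920 for tpst-1 against wild type (1465 and 443), 1987 and 1586 for tpst/psyr1,2,3 against tpst-1 (1073 and 2027), 413 and 616 for PSY5 in shoots (273 and 796), 593 and 412 for PSY5-treated tpst-1 against wild type (734 and 323), 132 and 400 for the interaction (74 and 501), 1237 and 1328 for 2 h (954 and 1687), 1552 and 1411 for 6 h (1242 and 1804), 1455 and 1463 for 24 h (1145 and 1819), 457 and 573 for the shoot minus root PSY5 effect (286 and 569) and 905 and 947 for the shoot minus root receptor-loss effect (419 and 902). Limma on log2(TPM + 1) gave 432 and 71 for psyr1,2,3 against wild type (185 and 192), 6000 and 820 for tpst/psyr1,2,3 against tpst-1 (1073 and 2027), 312 and 265 for PSY5 in shoots (273 and 796), 1549 and 197 for tpst/psyr1,2,3 against wild type (745 and 714), 651 and 125 for PSY5-treated tpst-1 against wild type (734 and 323), 541 and 195 for the shoot minus root PSY5 effect (286 and 569) and 1940 and 387 for the shoot minus root receptor-loss effect (419 and 902).

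With each library left out in turn, counts ranged over 2384 to 2649 for PSY5 in roots, 2323 to 2527 for receptor loss in roots, 47 to 141 for receptor loss against PSY5 in roots, 1368 to 2149 for tpst-1 against wild type, 113 to 362 for psyr1,2,3 against wild type, 845 to 1305 for tpst/psyr1,2,3 against wild type, 587 to 989 for PSY5-treated tpst-1 against wild type, 436 to 756 for the interaction, 2255 to 3948 for tpst/psyr1,2,3 against tpst-1, 546 to 1655 for PSY5 in shoots, 28 to 108 for tpst/psyr1,2,3 against psyr1,2,3, 1922 to 2293 for 2 h, 2350 to 2844 for 6 h, 2264 to 2684 for 24 h, 2948 to 3791 for 7 d, 4282 to 4865 for any change over time, 520 to 1147 for the shoot minus root PSY5 effect and 822 to 1609 for the shoot minus root receptor-loss effect.

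Replicate numbers did not pair libraries across groups. The median correlation of residuals of equal numbers was 0.013 in roots, 0.00173 in shoots and -0.0146 in seedlings, and a block for the number moved no count past 1.5 times. Of 401 list tests 205 passed, 40 with an estimated correlation and 204 with the block. With the tpst-1 shoot libraries split 2 and 2 the correlation of receptor loss and PSY5 had a mean of 0.287, against 0.692.

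Of the named values, 1082 stayed and 202 lost the call under limma on log2(TPM + 1), 1153 and 131 under quantile normalization, 1220 and 39 with DESeq2 and 1158 and 125 with the compared groups alone. SCR in tpst/psyr1,2,3 shoots against tpst-1 went from -0.36 to 0.023, 0.028, 0.011 and 0.023 under limma with pseudocounts of 1, 0.1 and 5 and without a trend, and AT4G12520 in the shoot minus root receptor-loss effect from -5.05 to 2.22 without shoot tpst-1 replicate 4 and -7.995 without shoot tpst/psyr1,2,3 replicate 4. Of 305 named seedling values 70 kept call and direction against 2 h, 156 lost the call and 79 had the other sign, 13 of those with a call.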

Other observations

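Seed storage genes, chosen after their values were seen, were high in shoots labelled tpst-1. The cruciferin gene CRA1 was at 125 ± 31 TPM there and 8.26 ± 16.5 TPM in wild type (log2 fold change 3.99 ± 1.03, adjusted p = 0.0146, n = 4 each). Its relative CRU3 was at 36.1 ± 11.7 and 1.06 ± 2.13 TPM, the oleosin gene OLEO2 at 19.0 ± 5.30 and 1.52 ± 2.89 TPM, and PER1 at 16.6 ± 2.08 and 1.2 ± 2.40 TPM. With PSY5, OLEO1 at 5.76 ± 2.08 TPM and M17 at 8.97 ± 9.26 TPM were lower (adjusted p = 0.00859 and 0.0464), while CRA1 at 78.1 ± 50.5 TPM, CRU3 at 21.2 ± 17.8 TPM, OLEO2 and PER1 did not pass (adjusted p = 0.582, 0.416, 0.102 and 0.134). In tpst/psyr1,2,3 shoots OLEO1, M17, CRU3, OLEO2 and PER1 were lower than in tpst-1 (adjusted p = 0.000159, 0.000277, 0.00714, 0.0166 and 0.0363), and CRA1 did not pass (adjusted p = 0.0577).

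AT1G78850 in roots and shoots, and AT3G05945 in shoots, were low where the labels name psyr1,2,3. AT1G78850 was at 180 ± 9.77 TPM in tpst-1 roots and 16.3 ± 1.66 TPM in tpst/psyr1,2,3 roots, and in shoots at 77 ± 12.9 TPM in wild type, 87.8 ± 29.1 in tpst-1, 12.5 ± 2.17 in psyr1,2,3 and 8.78 ± 1.95 in tpst/psyr1,2,3. AT3G05945 was at 42.1 ± 5.29 TPM in wild-type shoots, 42.2 ± 7.21 in tpst-1, 4.54 ± 2.99 in psyr1,2,3 and 2.32 ± 1.33 in tpst/psyr1,2,3.

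TPST stood at 2.81 ± 0.290 TPM in 0 h seedlings, 9.59 ± 2.26 TPM in tpst-1 roots and 6.70 ± 1.59 TPM in tpst-1 shoots, groups whose kits are not given in the sources used here.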
